A study of Oryza sativa Indica Group with 226 samples.

How the data were processed

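Shoots of 110 recombinant inbred lines and of their parents Minghui 63 and Zhenshan 97 were profiled on 226 Affymetrix Rice Genome arrays, 220 of lines (2 per line) and 6 of parents (3 each). Per the labels' protocols, seeds were soaked for 48 h at 25 °C, pre-germinated at 35 °C, checked every 2 h and grown for 72 h at 25 °C in the dark at 85% relative humidity, and RNA was extracted with Trizol and labelled with the standard Affymetrix protocol. Per the submitters' processing notes, RMA and the affy package were used; versions, settings and the role of each are not given in the sources used here. The deposited values are on the log2 scale, 1 per probe set and array with 2 decimals, running from 1.16 to 14.35 with array medians from 4.77 to 5.07, and were used as given. All 226 columns were matched to a sample.

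Control probe sets (123 with the AFFX prefix and 64 with the RPTR prefix) were left out of the tests, as were probe sets with a mean under 5 over all arrays, which left 27735 of 57194. The platform annotation gave 22436 probe sets 1 gene, 95 several and 34850 none; no gene was named from a probe set with several. The genes of all 22436 probe sets were found by gene identifier in the reference table of assembly ASM3414082v1, which served for symbols, synonyms, chromosomes and gene order only. A usable name (a symbol or synonym that is not a locus or clone identifier) was found for 3152 probe sets of 2425 genes, so most differences stay unnamed. Symbols in the table vary by source; the text uses the more common synonym where there are several. ARD1 is listed with the synonym HSFA2C and was not interpreted.

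The comparisons and alternatives were fixed before the data were examined, except where stated. Parents were compared with limma 3.58.1 (lmFit and eBayes, 3 against 3 arrays, in R 4.3.3 with the package data.table, version 1.17.8), with Benjamini-Hochberg adjustment, an adjusted p under 0.05, and counts with a log2 difference of at least 1. All adjusted p-values between the parents are from limma. Variation between lines was tested by an F test over 110 line means with the residual variance moderated by limma; repeatability is the difference of the mean squares between and within lines divided by their sum, so it can be negative. Line identity was checked by correlating each replicate 1 array with each replicate 2 array after subtracting the mean of each replicate number. The segregation index and the share of lines nearer to Minghui 63 used the probe sets with a parental difference of at least 1, with jackknife SEs over 11 blocks of 10 lines. A line was transgressive if its mean lay beyond the nearer parent by more than the moderated t quantile at a one-sided 0.05 divided by 220. The mean of the line means was set against the mid-parent with a moderated residual variance over all 226 arrays. Co-variation was computed for 1 probe set per gene. It was planned in megabases, but the annotation names no genome build, so the number of genes between a pair replaced it; the bins in megabases were not run.

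Gene lists were planned by description. The annotation holds no descriptions, so members were matched by symbol and synonym before any test; 21 planned lists had measured members and 8 lists were added after the annotation was seen (heat shock factors, cell cycle, jasmonate, aquaporins, metal uptake, calcium sensors, protein folding in the endoplasmic reticulum, abscisic acid and late embryogenesis). Starch breakdown had 0 measured members, and NB-ARC resistance, pentatricopeptide repeat, UDP-glycosyltransferase and transposon-derived lists could not be formed from symbols. After members and values had been seen, entries matched through a synonym of another gene were taken out of the seed storage, core histone and heat shock protein lists for their identity. GF14E, matched through its synonym GID2, was left in the F-box and gibberellin lists and counts among their members. The metal list misses Nramp1, whose spelling was not matched. Lists were tested with camera (preset correlation 0.01, and an estimated correlation) between the parents, and with a two-sided Fisher's exact test on the share of members with a repeatability of at least 0.5 between the lines, with 1 probe set per gene.

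Named genes followed a rule fixed before the data were examined: for the parents the 12 largest differences in each direction among called, non-overlapping, named probe sets, every measured trait gene and root marker, and up to 4 called members per other list; for the lines the 10 largest variance components and up to 3 members per list with the highest repeatability, of which mainly those passing the test are given; the 8 genes with most transgressive lines; and the 5 largest departures from the mid-parent in each direction. Genes with the largest shift between replicate numbers, the iron group, the 10 named genes with the largest correlation with it and NAS3 were chosen after the values were seen.

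The procedures were tested on simulated data for the 27735 probe sets. Noise was drawn independently for each array, without the shift between replicate numbers that the line arrays show. The recovery, false calls and index below therefore do not cover the effect of that shift on the fits without a block. Between the parents, 11% of 200 probe sets changed by log2 1 and 79.5% of 200 changed by log2 2 were recovered, with 2 and 4 false calls. Between lines 100% (1 locus) and 97% (4 loci) were recovered with 19 false calls, and the index returned 1.01 and 3.99. Transgression was recovered in 99.5% with 83 probe sets called without a shift, and a mid-parent shift of 1 in 95.5% with 11 false calls; 0 lists were called where none differed, and 110 lines were matched to themselves.

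Alternatives were: no filter or a mean of at least 7; arrays centred on their median; the replicate number as a block; an intensity trend in limma; all 226 arrays in the fit; each parent array left out in turn, 20 line arrays drawn and left out in turn; lines without a mutual best match left out; a stricter transgression threshold; a parental difference of at least 2; Spearman correlation; an estimated correlation in camera; and a repeatability of at least 0.7. Added after the data were seen were the block in the segregation results and, for transgression, line arrays centred within each replicate number. Also added were the lines of 1 replicate number alone, the block with the actin control as a covariate and near-identical lines counted as 1. Different transcript clusters, and distance in genes and repeatable genes in the co-variation, were added too. With 1 parent array left out the remaining 2 arrays of that parent were tested in the same limma fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.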

Results

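Transcript levels were measured with 226 Affymetrix Rice Genome arrays in shoots of dark-grown rice seedlings, 72 h after germination. The samples were 110 recombinant inbred lines (RILs, inbred progeny of 1 cross) from the indica varieties Minghui 63 and Zhenshan 97, with 2 arrays per line, and the parents, with 3 arrays each. The array carried 57381 probe sets, of which 27735 had a mean of at least 5 on the log2 scale and were tested. They covered 14621 annotated genes, 2100 of them with a usable gene name. The deposited log2 values ran from 1.16 to 14.35, and the median of an array lay between 4.77 and 5.07. The number of arrays (3 per parent, 2 per line) limits the precision. The study asks how transcript levels vary between the lines and which parental differences they inherit.

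Minghui 63 and Zhenshan 97 differed in TAC1, a regulator of tiller angle on chromosome 9, which measured 10.77 ± 0.065 (SD, n = 3) in Minghui 63 and 5.27 ± 0.45 in Zhenshan 97 (log2 difference 5.49, SE 0.23, adjusted p = 1.17e-05). The cystatin gene OC-X was higher in Minghui 63 by 4.50 (SE 0.21, adjusted p = 1.93e-05). NAAT1, the nicotianamine aminotransferase of phytosiderophore synthesis, was higher by 3.07 (SE 0.59, adjusted p = 0.0187), and the aluminium transporter gene Nrat1 by 3.05 (SE 0.25, adjusted p = 0.000453). The allantoinase gene ALN was higher by 3.02 (SE 0.26), STLP5 by 2.67, the apyrase gene APY3 by 2.40 and the Dicer-like gene DCL2A by 2.05. ABA8OX1, an abscisic acid 8'-hydroxylase gene, was higher by 1.85, the phosphate transport gene PHO1;2 and the bHLH gene RAI1 by 1.70 each, and the kinesin gene KIN14M by 1.63.

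In the other direction, a peroxidase gene on chromosome 7 measured 3.89 ± 0.61 in Minghui 63 and 8.45 ± 1.20 in Zhenshan 97 (log2 difference -4.56, SE 0.59, adjusted p = 0.00382). EIL1, of the ethylene-insensitive3-like family, differed by -4.14 (SE 0.30, adjusted p = 0.000252) and OrysaZxb by -4.08 (SE 0.23, adjusted p = 6.4e-05). The plasma membrane aquaporin gene PIP2;7 differed by -3.23 (SE 0.23, adjusted p = 0.000204) and the protein phosphatase gene PP2C68 by -3.21 (SE 0.74, adjusted p = 0.0362). Next came the heat shock factor gene HSFC2A (-2.67), BURP16 (-2.59), the tonoplast aquaporin gene TIP1;2 (-2.51) and the pectin methylesterase inhibitor gene PMEI28 (-2.41). The Rubisco small subunit gene rbcS, the nicotianamine synthase gene NAS3 and the beta-glucosidase gene BGLU5 each differed by -2.17, with rbcS at 10.02 ± 0.056 in Minghui 63 and 12.19 ± 0.095 in Zhenshan 97. The Tag control probe sets, which match no rice transcript, averaged 2.55 to 4.63 on the parent arrays. The Minghui 63 levels of the peroxidase gene, EIL1 (4.23) and BGLU5 (4.47) and the Zhenshan 97 level of NAAT1 (4.49) lay in that range. Their differences may therefore be lower bounds, and their order is not known. For EIL1 the line means reached 3.795, under its Minghui 63 level.

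In all, limma called 2917 probe sets between the parents at an adjusted p under 0.05, 1367 higher in Minghui 63 and 1550 higher in Zhenshan 97. A log2 difference of at least 1 remained in 1534 of them, 607 higher in Minghui 63 and 927 (60.4%) higher in Zhenshan 97, covering 929 annotated genes. In all 1534 the 3 values of each parent did not overlap; over all tested probe sets 8952 (32.3%) did not overlap, against 10% from chance alone. The count at an adjusted p under 0.05 varied with single arrays and with the arrays fitted. With all 226 arrays in the fit it was 1393. That fit counts the shift between the replicate numbers of the lines, described below, as residual variance. Its count therefore does not rest on the spread of the parent arrays alone. The count was 1164 without Minghui 63 replicate 2 and 1375 without Minghui 63 replicate 1. It was 1493 without Zhenshan 97 replicate 1 and 1539 without Zhenshan 97 replicate 2. Without Minghui 63 replicate 3 it was 2723, and without Zhenshan 97 replicate 3 it was 3146. With the log2 limit these fits gave 1076 to 1817. The replicate number as a block gave 934, or 929 with the log2 limit, though parent arrays of the same number showed no shared deviation. With a mean of at least 7 the count with the log2 limit was 909.

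Of 8 measured genes for light harvesting and photosynthesis, 7 were lower in Minghui 63 (7 adjusted over the list alone), with a median log2 difference of -1.08. They included rbcS, the photosystem I gene PSAH (-1.79), PSB28 (-1.35) and the chlorophyll a/b binding protein gene CAB2R (-1.09). Of 11 genes for chlorophyll synthesis, 6 were lower (9 adjusted over the list alone; median -0.75). CHLH, a magnesium chelatase subunit gene, differed by -1.20, the protochlorophyllide reductase genes PORB and PORA by -1.09 and -0.88, and CHLP by -0.79. The camera test gave adjusted p = 1.98e-08 for the photosynthesis list and 9.85e-07 for the chlorophyll list with a preset correlation of 0.01; adjusted p = 0.263 and 0.462 with an estimated correlation.

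Of 20 aquaporin genes 4 were lower in Minghui 63 (6 adjusted over the list alone; median -0.27), among them PIP2;7, TIP1;2, PIP1;3 (-1.22) and the silicon channel gene Lsi1 (-0.67, adjusted p = 0.0242). Of 6 glutathione S-transferase genes 2 were lower (4 adjusted over the list alone; median -0.47), GSTZ5 (-1.45) and GSTU6 (-0.60). Of 14 pathogenesis-related and protease inhibitor genes 1 was higher, OC-X, and 3 were lower (5 adjusted over the list alone; median -0.32): OC-II (-1.28), Cht1 (-0.997) and Cht3 (-0.57). Of 8 abscisic acid and late embryogenesis genes 1 was lower (3 adjusted over the list alone; median -1.88), LEA3, at -2.02 (adjusted p = 0.0143). Of 35 genes for metal uptake and chelation 2 were higher and 8 lower (18 adjusted over the list alone), with NAAT1 and ZIP3 (1.40) higher and NAS3 and the metallothionein gene MT1B (-2.00) lower. Of 46 cell cycle and DNA replication genes 1 was higher, CDC2-2 (0.58; 0 adjusted over the list alone). The camera adjusted p with the preset correlation was 0.00396 for aquaporins, 0.0199 for glutathione S-transferases, 0.0199 for abscisic acid and late embryogenesis, 0.0422 for metal uptake (tested as lower, with a median of -0.06), 0.0447 for pathogenesis-related genes and 0.0447 for cell cycle genes (tested as higher, median 0.26). With an estimated correlation these were adjusted p = 0.621, 0.463, 0.671, 0.506, 0.463 and 0.727, so 8 lists passed with the preset correlation (3 with a mean of at least 7) and 0 with the estimated one; 10 of the 29 lists had an unadjusted p under 0.05 with the preset correlation.

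Wall genes moved both ways: of 47 measured, 7 were higher in Minghui 63 and 2 lower (14 adjusted over the list alone), including the expansin genes EXPB8 (1.19) and EXPB11 (-0.80) and the cellulose synthase-like genes CSLC7 (0.89) and CSLD2 (0.86). Of 11 receptor-like kinase genes 3 were higher (3 adjusted over the list alone): CHARK (1.02), BAK1 (0.79) and the chitin receptor gene CERK1 (0.61). Of 25 auxin response genes 3 were higher (3 adjusted over the list alone): IAA14 (1.05), IAA12 (0.92) and IAA18 (0.70). Of 6 photoreceptor and light signalling genes 2 were higher (4 adjusted over the list alone), PHOT1A (1.17) and PHYA (0.69). Of 13 peroxidase genes 3 were lower (4 adjusted over the list alone): the chromosome 7 gene, APX8 (-1.74) and PRXIIE-2 (-0.93). Of 27 calcium sensor genes CML9 (0.93) and CML11 (0.86) were higher and CML8 (-1.94) and CML1 (-1.87) lower (4 adjusted over the list alone). Of 20 cytochrome P450 genes ABA8OX1 was higher and ABA8OX2 (-0.93) lower (2 adjusted over the list alone), and of 17 heat shock factor genes HSFC1A (1.27) was higher and HSFC2A lower (2 adjusted over the list alone). Of 23 cytosolic ribosomal protein genes RPL27 (-0.87) and RPL18 (-0.83) were lower (2 adjusted over the list alone). Of 16 genes for protein folding in the endoplasmic reticulum DJC79 (0.69) and PDIL5-2 (0.59) were higher (4 adjusted over the list alone), as were 1 of 24 jasmonate genes, JAZ1 (0.67; 1 adjusted over the list alone), and 1 of 8 diterpenoid phytoalexin genes, MAS (1.03; 1 adjusted over the list alone).

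Of the 2 root markers, Lsi1 was lower in Minghui 63 and IRT1 was not called (adjusted p = 0.271; 1 adjusted over the list alone), with both parental levels in the range of the Tag controls, so that its parental difference could not be measured. Among 12 known trait genes, PHYA, PORA and PORB were called (3 adjusted over the list alone). The others were not: BRI1 (0.35, adjusted p = 0.205), the brassinosteroid gene D11 (0.42, adjusted p = 0.113), the semidwarf gene SD1 (-0.49, adjusted p = 0.186), the gibberellin receptor gene gid1 (-0.14), SLR1 (0.04), phyC (0.20), PhyB (0.35), IPA1 (0.15) and Adh2 (-0.09). No gene was called among 4 seed storage, 6 heat shock protein, 5 oxygen limitation, 5 F-box, 2 core histone, 16 proteasome and 13 gibberellin genes, and 0 were called in these lists adjusted over the list alone. Outside the 8 lists above, the camera adjusted p ran from 0.0893 (peroxidases and root markers) to 0.842 (oxygen limitation) with the preset correlation and from 0.463 to 0.917 with the estimated one. For gibberellin, trait and heat shock factor genes camera tested as lower while the median was 0.04, 0.10 and 0.05. The calls of CSLD2, CERK1, PHYA and CDC2-2 were lost in each of the 6 fits without 1 parent array, and those of ABA8OX1, PP2C68, CHARK, ABA8OX2, GSTU6, MAS, Cht1, Cht3, IAA18, DJC79 and PDIL5-2 in 5 of the 6. With all 226 arrays in the fit 38 of the 68 called named genes lost the call: DCL2A, PHO1;2, KIN14M, BGLU5, PSAH, CHLH, PORB, PORA, CHLP, EXPB8, CSLC7, EXPB11, CHARK, BAK1, CERK1, ABA8OX2, GSTU6, APX8, MAS, Cht1, Cht3, IAA14, IAA12, IAA18, PHOT1A, PHYA, Lsi1, HSFC1A, CDC2-2, JAZ1, PIP1;3, MT1B, ZIP3, CML9, CML11, DJC79, PDIL5-2 and LEA3. The fit with all arrays counts the shift between the replicate numbers of the lines as residual variance. A call lost there can therefore come from the line arrays. Without either replicate 3, 5 lists in place of 8 passed camera.

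Among the lines, 4 genes of iron acquisition varied over wide ranges, and NAS3 did not pass the test (line means 8.57 to 9.83, adjusted p = 1). The nicotianamine synthase genes NAS1 and NAS2 had line means between 2.22 and 12.79 and between 5.26 and 12.34, with repeatabilities (the share of variance between lines) of 0.701 and 0.716. Line means of the iron transporter gene IRT2 ran from 3.85 to 10.02 (repeatability 0.731) and those of IRT1 from 3.92 to 8.24 (0.682). These 4 genes were not called between the parents, except IRT1 without Minghui 63 replicate 3; NAS1 measured 4.09 ± 1.18 (SD, n = 3) in Minghui 63 and 3.21 ± 0.68 in Zhenshan 97 (adjusted p = 0.413). Both parental levels of NAS1 and IRT1 and the Zhenshan 97 level of IRT2 (3.96) lay in the range of the Tag controls, so the missing call says little about the parents there. The moderated F test over 110 line means gave adjusted p = 5.94e-17 for NAS1, 5.7e-18 for NAS2, 5.85e-19 for IRT2 and 1.66e-15 for IRT1.

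Several genes called between the parents also varied between the lines. TAC1 had a repeatability of 0.949 (line means 5.42 to 10.71, adjusted p = 1.08e-55), OrysaZxb 0.928, the meiotic recombination gene SPO11-4 0.849, EIL1 0.786, TF1 0.75 and OC-X 0.745. NAAT1 reached 0.429, rbcS 0.412, the light-harvesting gene LHCP on chromosome 3 0.406, CAB2R 0.393, CHLP 0.343, CML1 0.293, PIP2;7 0.293 and the metallothionein gene MT4A 0.268. Other genes varied between the lines without being called between the parents: CYP701A19, which carries the ent-kaurene oxidase synonym KO2 (0.581), the pyruvate decarboxylase gene PDC2 (0.493), DJC27 (0.477), the ascorbate peroxidase gene APX1 (0.456), PCL1 (0.422), the expansin gene EXPB3 (0.407), XTH8 (0.403), IAA19 (0.388), IAA7 (0.355), the salt-induced lectin gene salT (0.355) and Agglutinin (0.285). All had an adjusted p under 0.05 in the F test. After each array was centred on its median, rbcS, CAB2R, EXPB3, XTH8, IAA19, IAA7, salT, CHLP, CML1, PIP2;7, Agglutinin and MT4A no longer passed. TIP2;1 and PM19L1, taken for their variance component among genes not named before, did not pass the F test (adjusted p = 0.325 and 0.373); with the replicate number as a block TIP2;1 passed (adjusted p = 0.0181).

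The F test called 1668 probe sets (6.01%), and 738 (2.66%) had a repeatability of at least 0.5. With a mean of at least 7 these were 768 and 262, and without a filter 2655 and 1228. With the replicate number as a block, 4430 (16.0%) were called, all 1668 among them, and 1246 (4.49%) reached 0.5. The median repeatability was -0.30 without the block and 0.06 with it, since the fit without it counts a shift between the replicate numbers as variance within lines. Of the genes named for the lines 20 gained the call with the block: TIP2;1, GluTR, PORA, HSP81-3, Adh2, CHARK, CYP88A5, GST-I, GSTZ5, GST-II, PRXIIE-2, CYP71Z6, SD1, HSF04, JAZ1, TIP4;1, Lsi6, CML4, PDIL5-2 and BIP1. Genes named for other results that gained it were DCL2A, PHO1;2, RAI1, the chromosome 7 peroxidase, PP2C68, TIP1;2, PSB28, EXPB8, CSLC7, EXPB11, GSTU6, APX8, OC-II, IAA12, PIP1;3, MT1B, CML8, DJC79, PAL06, AtMAP70-4, ADC1 and Nramp1. The blocked repeatability was 0.937 for OC-X, 0.807 for NAAT1, 0.662 for the HSP90 gene HSP81-3, 0.650 for PIP2;7 and 0.619 for SD1, and was 0.70 for NAS1. Of the probe sets with a parental log2 difference of at least 1, 32.5% had a repeatability of at least 0.5 (45.3% with the block), against 0.916% of the others (2.1% with the block). In the metal uptake list 6 of 35 genes (17.1%) reached 0.5, against 2.47% of other genes (Fisher's exact test, two-sided, adjusted p = 0.0061; 10 of 35 with the block). NAS1, NAS2, IRT1 and IRT2 were among the 6 and are not independent. Over the lines NAS1 and NAS2 correlated at 0.987 within replicate 1 and 0.966 within replicate 2. Fisher's test counts such genes separately, so its p may be too small. Of 29 lists metal uptake was the only one to pass, and 2 had an unadjusted p under 0.05. With a mean of at least 7, or a repeatability of at least 0.7 (8.57% of metal members), 0 lists passed. The other was root markers, with 1 of 2 genes (Fisher's exact test, p = 0.0496, adjusted p = 0.719). All other lists had an adjusted p of 1.

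**Figure D1:**
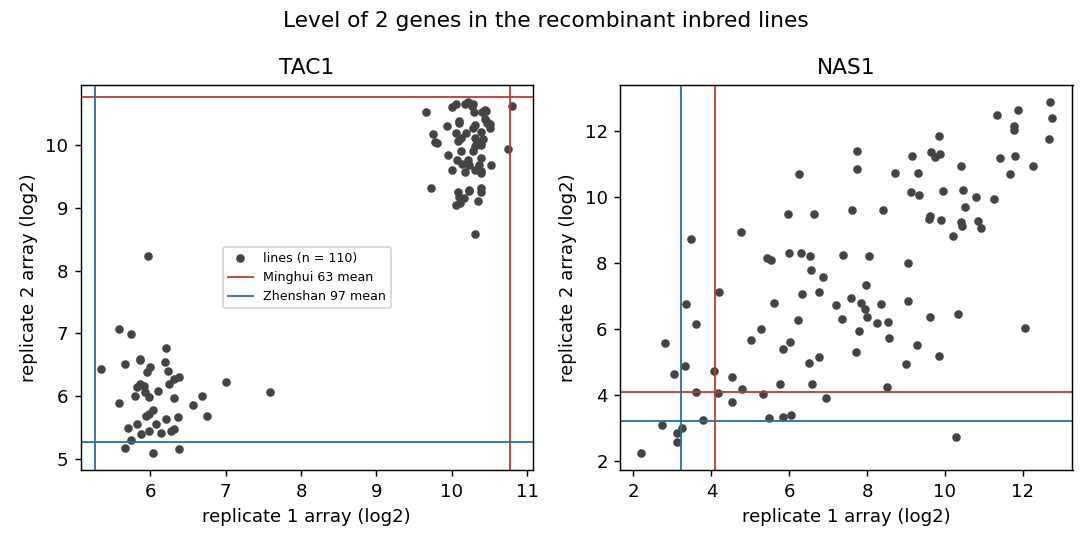
Level of TAC1 and NAS1 (log2) in the replicate 1 array (horizontal axis) and the replicate 2 array (vertical axis) of each of the 110 lines, with the means of Minghui 63 and Zhenshan 97 as lines. TAC1 falls into 2 clusters near the parental means, while NAS1 spreads from 2.22 to 12.79 in line mean, beyond both parents.

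The replicate 2 arrays of the lines differed from the replicate 1 arrays in many genes. The clock gene PRR73 differed by -2.69 (log2, replicate 2 minus replicate 1), the cellulose synthase genes CESA1 and CESA2 by -2.53 and -2.26, the Argonaute gene AGO1B by -2.50 and the translation initiation factor gene eIF-4G by -2.49. The calmodulin-like genes CML27 and CML29 differed by 2.06 and 1.94, CASPL2B1 by 1.96, the lipid transfer protein gene LTP-2 by 1.89 and MT1B by 1.81. In total 4455 probe sets shifted by at least 1, 1377 up and 3078 down; the median of the tested probe sets itself shifted by -0.21, and after centring each array 4180 shifted, 2207 up and 1973 down. These are differences of means over 110 arrays on each side, given without a test. The first principal component held 49.8% of the variance and separated 110 of 110 replicate 1 arrays and 97 of 110 replicate 2 arrays by its sign. The actin control's 3' minus 5' difference was 1.06 ± 0.23 (SD, n = 110) in replicate 1, 2.08 ± 1.23 (n = 110) in replicate 2 and 2.1 ± 0.39 (n = 6) on the parent arrays, with 2.13 ± 0.085 (n = 3) in Minghui 63 and 2.06 ± 0.60 (n = 3) in Zhenshan 97. The labels do not say whether a replicate number stands for a shared day or batch.

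**Figure D2:**
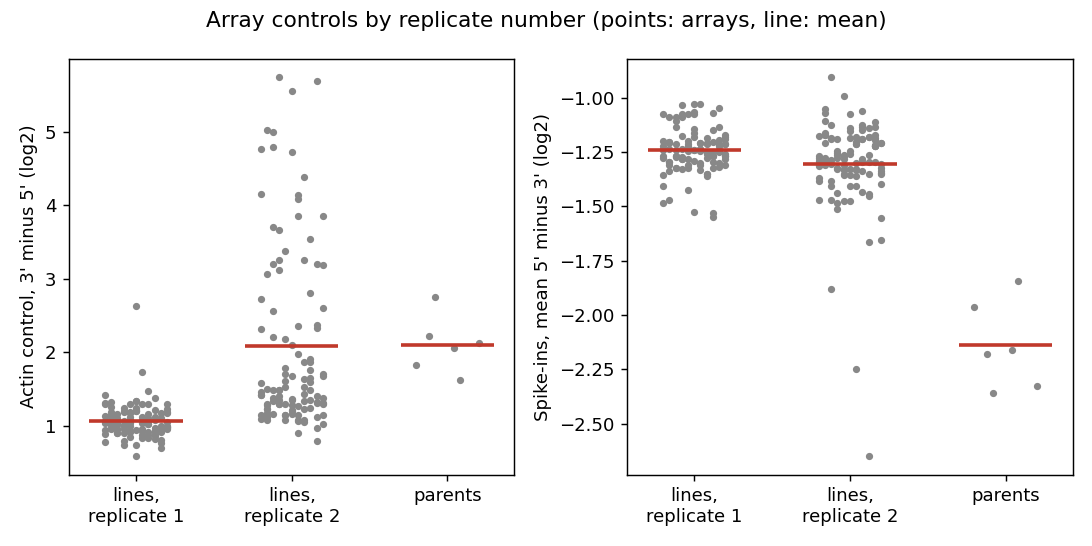
Actin control 3' minus 5' difference and mean 5' minus 3' difference of 4 spike-in controls (log2, vertical axes) for lines in replicate 1, lines in replicate 2 and the parents; points are arrays and bars are means. The actin difference has a mean of 1.06 in replicate 1 and 2.08 in replicate 2 of the lines, and the spike-in difference averages -2.14 on the parent arrays against -1.24 and -1.30 on the line arrays.

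Arrays of the same line matched each other over the 1534 probe sets that differed between the parents. The correlation of a line's 2 arrays had a median of 0.805 (range 0.552 to 0.905), and 98 of 110 lines (89.1%, exact 95% interval 81.7 to 94.2) were mutual best matches. The 12 remaining lines all belonged to 11 pairs of lines that matched each other above 0.6 within both replicate numbers, such as RIL111 with RIL204 (0.943 in replicate 1 and 0.823 in replicate 2), RIL026 with RIL027 and RIL161 with RIL162. The next closest pair reached 0.514. These are correlations across probe sets, which are not independent replicates.

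Parental differences segregated in the lines to unequal degrees. For TAC1, 58.2% of lines were nearer to Minghui 63, for OC-X 67.3%, for EIL1 52.7% and for OrysaZxb 40%. The parental difference of Nrat1 was not seen among the lines: 0% were nearer to Minghui 63, with line means between 4.41 and 5.66 and a blocked repeatability of -0.02. For ALN 7.27% were nearer, with line means between 5.95 and 8.07 and a blocked repeatability of 0.696. For rbcS, NAS3 and the chromosome 7 peroxidase 0% of lines were nearer to Minghui 63, and for TIP1;2 and HSFC2A 100% and 99.1%. These shares set line arrays against parent arrays, which had a lower mean 5' minus 3' difference of the spike-in controls than both sets of line arrays (-2.14 against -1.24 and -1.30). The same 5 genes departed from the mid-parent, by 1.03 (rbcS), 0.84 (NAS3), 1.26 (peroxidase, possibly a lower bound), -1.32 (TIP1;2) and -1.11 (HSFC2A). The limit therefore holds for the shares, for transgression and for the departures from the mid-parent below. The index set the squared half-difference of the parents against the variance between lines, and is 1 for a single locus of full effect. Its median was 8.41 (jackknife SE 1.16), 3.92 (SE 0.175) with the replicate block, and 1.70 (SE 0.057) for the 452 probe sets with a parental difference of at least 2 (1.58 with the block). The median depended on single parent arrays: it was 5.16 without Minghui 63 replicate 2, 14.3 without Minghui 63 replicate 3 and 14.1 without Zhenshan 97 replicate 3. It was 4.86 without a filter and 18.0 with a mean of at least 7. An index under 1.5 was found for 319 probe sets (20.8%), and 497 (32.4%) had no positive variance component; with the block these were 395 (25.7%) and 35 (2.28%). The median share of lines nearer to Minghui 63 was 39.1% (SE 1.47; 25.5% without Minghui 63 replicate 3 and 18.2% with a mean of at least 7), 49.1% where Minghui 63 was higher and 24.5% where Zhenshan 97 was higher. For the 695 probe sets with a blocked repeatability of at least 0.5 it was 49.1%, and over those of them with a mapped gene, 15 to 63 per chromosome, chromosome medians ran from 41.8% (chromosome 7) to 59.1% (chromosome 11).

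Some genes lay outside both parents in many lines. The germin-like gene GER8 was above both parents in 104 of 110 lines, the kinase gene WNK7 in 93, the sugar transporter gene SWEET14 in 84, the phenylalanine ammonia-lyase gene PAL06 in 77, the silicon transporter gene Lsi6 in 68, AtMAP70-4 in 68 and the arginine decarboxylase gene ADC1 in 67. The vacuolar iron transporter gene VIT2 was below both parents in 72 lines. In total 2327 probe sets had at least 1 transgressive line, 1128 above and 1202 below (3 in both). Of these, 350 had at least 10 such lines and 1082 had 1. The threshold adjusts over the lines and both directions within a probe set, with no adjustment over the 27735 probe sets. The count was 4491 without a filter, 1469 with a mean of at least 7 and 1443 at a stricter threshold. With the line arrays centred within each replicate number the count was 6238, 2971 above and 3278 below. The parent arrays were left as given, so this takes the shift out of the spread only. The difference between lines and parents can still hold it. The 8 named genes kept their direction with this centring, in 73 (Lsi6) to 104 (GER8) lines, VIT2 in 84.

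The mean of the lines departed from the mid-parent in the following named genes; no list was tested for it. Both parental levels of NAS1 and the Zhenshan 97 level of NAAT1 lay in the range of the Tag controls, and the lowest line means of both lay in it or under it, so the size of their departure is not exact. NAS1 was higher in the lines by 3.97 (SE 0.65, adjusted p = 9.53e-07), NAAT1 by 3.04 (SE 0.46), the metal transporter gene Nramp1 by 2.76 (SE 0.47) and MT4A by 2.57 (SE 0.47). CESA1 was higher by 3.17 (SE 0.92, adjusted p = 0.0072), by 4.43 in replicate 1 and 1.91 in replicate 2. Lower in the lines were LEA3 (-3.50, SE 0.75, adjusted p = 0.000178), the dehydrin genes RAB21 (-2.91, SE 0.67) and RAB16B (-2.68, SE 0.71), LTP-2 (-2.57, SE 0.65; -3.51 in replicate 1 and -1.62 in replicate 2) and VIT2 (-2.43, SE 0.20). RAB16B was not called without Zhenshan 97 replicate 1.

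In all, 5472 probe sets departed from the mid-parent, 2960 above and 2512 below it, and 965 by at least 1 (752 above, 213 below). With each array centred on its median 5592 departed, 2222 above and 3370 below (630 and 278 by at least 1), so the share above was 39.7% in place of 54.1%; 4388 probe sets were called both ways. The median of the tested probe sets was 0.19 higher in replicate 1 of the lines than on the parent arrays and -0.02 in replicate 2. With the replicate block 8476 were called, 4465 above and 4011 below. That fit takes the shift of the line arrays as shared by parent arrays of the same number, which showed no shared deviation. Its mid-parent rests on replicates 1 and 2 of the parents, since only parents had a replicate 3. The count was 11942 without a filter, 3076 with a mean of at least 7, 16727 with the replicate 1 lines alone and 14486 with the replicate 2 lines alone, and the share above was under 50% in 3 of these (47.7%, 45.1% and, for replicate 2, 46.7%).

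Parental differences of neighbouring genes varied together over the lines. Over 929 genes, the median correlation of a pair, taken between replicate numbers and signed by the parental difference, was 0.146 (SE 0.016) with fewer than 100 genes between them. It was 0.107 for 100 to 500 genes, 0.074 for 500 to 1000, 0.059 for 1000 to 2000, 0.049 beyond 2000 and 0.041 (SE 0.0079) on different chromosomes. For the 361 genes with a blocked repeatability of at least 0.5, a restriction chosen after the values were seen, the medians were 0.686, 0.425, 0.169, 0.076, 0.026 and 0.0082.

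**Figure D3:**
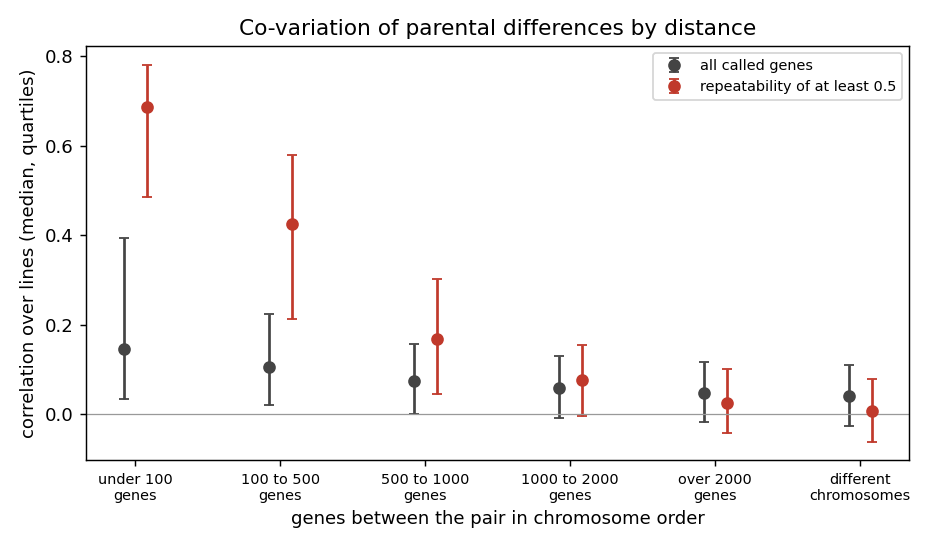
Median correlation over lines (vertical axis, bars from the first to the third quartile) of gene pairs that differ between the parents, by the number of genes between them in chromosome order (horizontal axis). The median falls from 0.146 to 0.041 over all 929 genes and from 0.686 to 0.0082 over the 361 repeatable genes.

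Probe sets of the same gene mostly moved in the same direction between the parents. In 178 genes with a called probe set and at least 1 further tested probe set, 203 of 226 further probe sets (89.8%, 95% interval 85.2 to 93.1, Wilson) had the same sign, and 115 were called, 113 of them with the same sign. Restricted to probe sets from different transcript clusters of the array design, a restriction chosen after the values were seen, it was 69 of 82 (84.1%, 74.7 to 90.5), with 30 called and 28 of those of the same sign.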

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

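Of the alternatives below, those added after the data were seen are named as added. Of 217 alternative values, 156 stayed within the limit (1.5 times for counts, the SE for medians, 10 percentage points for shares of calls, the 95% interval for identity, same-sign and metal shares) and 61 moved. Among them only the co-variation could change sign, and it did not. No called parental, transgression or mid-parent value of a named gene changed sign. The mid-parent share above crossed 50% in the settings named here. Without a filter the lines gave 2655 called and 1228 repeatable probe sets, the index 4.86, the share nearer to Minghui 63 43.6%, transgression 4491, the mid-parent 11942 (47.7% above), co-variation 0.199 and same-sign probe sets 83.1%. With a mean of at least 7 these were 768, 262, 18.0, 18.2%, 1469, 3076 (45.1% above) and 0.121 (0.0593 on different chromosomes), with 909 parental calls, 3 lists between the parents and 0 between the lines; fewer probe sets were tested. Of the results run with centred arrays the mid-parent share above moved, to 39.7%, and of named genes 15 line values lost and 7 gained the call, and 6 parental values lost it. With all 226 arrays in the fit the parental calls at an adjusted p alone were 1393. That fit counts the shift between the replicate numbers of the lines as residual variance. The stricter threshold left 1443 transgressive probe sets, a parental difference of at least 2 an index of 1.70 and a share of 49.1%, the estimated correlation 0 lists, and a repeatability of 0.7 0 lists between the lines. The line arrays of 1 replicate number shared a shift: deviations of line pairs correlated above 0.1 in 99.4% of 5995 pairs (median 0.705, lowest -0.156). Those of the parents correlated at -0.31, -0.07 and -0.39, so the parent arrays showed no such shared deviation. The fit without the block, fixed beforehand, was kept as the reported one. For the lines it counts the shared shift as variance within lines, so the blocked values below belong beside it. With the replicate block the parents gave 929 (934 at an adjusted p alone), the lines 4430 and 1246, and the mid-parent 8476. That mid-parent count rests on the parents' replicates 1 and 2 and on a shift taken as shared with the lines. Added were an index of 3.92 with the block, and 5297 and 1453 for the lines with the block and the actin covariate. Line arrays centred within each replicate number, also added, gave 6238 transgressive probe sets. The block also left 35 in place of 497 parental probe sets without a positive variance component, and 10 in place of 6 metal genes past the repeatability limit. Also added: the mid-parent gave 16727 with replicate 1 lines alone and 14486 with replicate 2 (46.7% above). These 2 counts used a residual variance from the 6 parent arrays alone in place of all 226 arrays. Added too, identity was 110 with near-identical lines as 1 (no test, since all 12 lines without a match belong to such pairs). Different clusters, also added, gave 84.1%, and repeatable genes a co-variation of 0.686 (0.00817 on different chromosomes). Leaving out 1 array gave 1164 to 3146 parental calls at an adjusted p alone (1076 to 1817 with the log2 limit), an index of 5.16 to 14.3, a share of 25.5% to 42.7%, 5 to 9 lists and a co-variation of 0.104 to 0.213. Of named genes, 226 of the parental values lost and 2 gained the call, most often with all arrays in the fit (38) or the block (36); for the lines 62 gained and 16 lost it, and for the mid-parent 1 lost it. The cause was not tested unless stated.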

Other observations

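The tests of 1 replicate number alone and of shuffles within a replicate number, the centring of the round shift, the relation of the first component to the controls, all tests on the iron genes, the different transcript clusters and the counts of the last paragraph were chosen after the result was seen; the other tests were fixed before it. For the 1534 parental calls, the 6 parent arrays can be split in 10 ways, too few for a share under 0.05; 1 split, the real one, gave as many, and the highest other gave 0. Shuffling line labels over the arrays gave as many as the 1668 called probe sets in 2 of 100 cases, the real one included, with a highest other of 3296. So 1 shuffle called more than the real lines. Such shuffles can place 2 arrays of 1 replicate number in a line, which the real lines never hold. The shift between the numbers can then count as variance between lines, so this test cannot judge the 1668. Shuffled within the replicate numbers as a block, 1 of 100 gave as many as 4430, with a highest other of 9, so chance was excluded there. For the mid-parent, 1 of 100 sets of 6 arrays, the real one, gave as many as 5472, with a highest other of 99 over random sets of line arrays. A separate fit set the 6 parent arrays as 1 group against the lines of 1 replicate number. There 1 of 100, the real one, gave as many as 18718 in replicate 1, with a highest other of 9563. In replicate 2 the count was 11230 against 4992. Random sets of line arrays thus did not reach the parents' counts. Such draws cannot exclude parent arrays processed apart, whose spike-in 5' minus 3' difference was -2.14 against -1.24 and -1.30 on the line arrays.

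The replicate 2 arrays of the lines differed from the replicate 1 arrays in the signal of both ends of control transcripts. The mean of the actin and gapdh 3' minus 5' differences was higher in replicate 2 in 90% of lines (99 of 110, 95% interval 82.8 to 94.9), in a test fixed beforehand, so a difference in RNA length or labelling may account for part of the shift. The spike-in 5' minus 3' difference was -1.24 and -1.30 in the replicate numbers. Levels of other controls also differed, replicate 2 minus replicate 1, given without a test. For rRNA the difference was 2.19 (25S), 2.24 (5.8S), 1.36 (28S) and 0.50 and 0.56 (18S). Over the probe sets of the dap, lys, phe and thr spike-ins it ran from 1.07 (dap) to 2.20 (lys). Over those of bioB, bioC, bioD and cre it ran from 0.18 (cre) to 0.74 (bioB). Within replicate 2 the first component of the arrays (32.6% of their variance) correlated over 110 arrays with that mean at a size of r = 0.728 and rho = 0.779 (permutation p = 1e-05 each, adjusted over 2 relations 2e-05 and 1e-05; 0.744 without the 2 farthest arrays), and within replicate 1 (21.2%) at r = 0.348 and rho = 0.469 (permutation p = 0.0007 and 1e-05, adjusted 0.0007 and 1e-05; 0.389 without them), relations examined after the values were seen. An overall scale difference alone is argued against, since 75.2% of the 4455 shifted probe sets (3350) still shifted after centring. A difference in growth between sowings stays open and was not tested.

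Some iron acquisition genes, a group of 6 chosen after the values were seen, varied together between the lines. The highest adjusted p of NAS1, NAS2, IRT1, IRT2, NAAT1 and Nramp1 in the F test with the replicate block, adjusted over all 27735 probe sets, was 7.13e-16 (without the block 5 of 6 passed, the highest being 0.0755), which argues against noise of single arrays. The root silicon channel gene Lsi1 was set against the group over 110 lines (r = -0.129, interval -0.308 to 0.060, permutation p = 0.0802; rho = -0.120, permutation p = 0.108; r = -0.112 without the 2 farthest lines), but Lsi1 did not pass the F test between lines (blocked adjusted p = 0.104) and was higher in them than the mid-parent, like IRT1 (0.58 and 0.93, adjusted p = 0.00179 and 0.000746, not exact for IRT1, whose parental levels lay in the range of the Tag controls), so root tissue in the samples stays open. The 4 pairs of near-identical lines that do not carry neighbouring numbers, chosen without probe sets that follow the group, were closer in it than random pairs (mean difference 0.409 against 0.987, permutation p = 0.0394), while 44 pairs with neighbouring numbers that are not near-identical differed by 1.10 (permutation p = 0.853), which argues, on 4 pairs only, against growth differences not tied to the genotype or seed lot; a shared seed lot stays open, and the best of 326 expression markers correlated at 0.732 (permutation p = 0.000999, the smallest possible), so a segregating locus may contribute. The 17 markers past the permuted limit lay on several chromosomes and may follow the iron response themselves, so no locus can be placed, and the higher level of these genes in the lines than in both parents cannot be told apart from parent arrays processed apart, whose spike-in 5' minus 3' difference was -2.14 (-2.36 to -1.85) against -1.24 (-1.55 to -1.03) in replicate 1 and -1.30 (-2.65 to -0.91) in replicate 2.

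Since the 6 members were chosen after the values were seen, the choice was repeated by a stepwise search. The best 6 of the 35 metal genes, 5 of them in the group, correlated between replicate numbers at a mean r of 0.632, against at most 0.308 for the best 6 of random lists of like repeatability (permutation p = 0.001, the smallest possible). All pairs of the metal list had a median of 0.0026 (permutation p = 0.452), so this holds for some members and not for the list. Of 2094 named genes set against the group, 21 passed the highest r of 100 permutations over all genes (0.372), and the 10 with the largest r are given. VIT2, which stores iron in vacuoles, ran against it (r = -0.671, rho = -0.679; r = -0.669 without the 2 farthest lines; -0.736 and -0.747 within replicates 1 and 2), as did APX1 (r = -0.639, rho = -0.640; -0.598 without them; -0.778 and -0.545). BHLH063, a basic helix-loop-helix gene, followed it (r = 0.635, rho = 0.627; 0.624 without them; 0.885 and 0.585). The methionine cycle gene MTK1 (r = 0.489, rho = 0.423; 0.432 without them; 0.747 and 0.292) and NAC071 (r = 0.474, rho = 0.431; 0.425 without them; 0.669 and 0.471) followed it too. ILL6 (r = -0.494, rho = -0.464; -0.444 without them; -0.593 and -0.361), Ip (r = -0.493, rho = -0.464; -0.446 without them; -0.582 and -0.440), CAD3 (r = -0.464, rho = -0.370; -0.400 without them; -0.615 and -0.380), the tetrapyrrole synthesis gene GluTR (r = -0.491, rho = -0.469; -0.450 without them; -0.730 and -0.451) and the chloroplast regulator gene GLK1 (r = -0.451, rho = -0.389; -0.398 without them; -0.631 and -0.432) ran against it. Each had a permutation p = 1e-05 for r and for rho, the smallest possible, or 0.000654 and 0.000805 adjusted over the 2094 genes. The nicotianamine synthase gene NAS3, under that limit and added for its family, ran the other way from NAS1 and NAS2 (r = -0.329, rho = -0.285; -0.292 without them; -0.328 and -0.359; permutation p = 2e-05 and 7e-05, adjusted 0.00116 and 0.00419), and did not pass the blocked F test between lines (adjusted p = 0.122). Over all 14615 genes outside the group, 24 had r of at least 0.5 and 27 of -0.5 or less, on 12 chromosomes.

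A base difference under the probes can imitate a parental difference in 1 probe set. Further probe sets of the same gene had the same sign in 89.8% of cases (lower bound 85.2%), above the 75% set beforehand. This argues against a base difference under 1 probe set alone as the general cause. It cannot judge base differences under several probe sets of a gene, which can shift them in the same direction. From different transcript clusters, a restriction added later, the share was 84.1% with a lower bound of 74.7%, just under that limit. For a single gene with 1 probe set a base difference stays open, as does the genotype of the parents, which the design does not separate from it.

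Of the 452 probe sets with a parental difference of at least 2, 376 had a blocked repeatability of at least 0.5 between the lines, with a median of 50.9% of lines nearer to Minghui 63. Another 26 had one under 0.25; in 10 of these fewer than 10% of lines, and in 8 more than 90%, were nearer to Minghui 63, Nrat1 among the former. Of the 326 markers, 278 (85.3%, 81.0 to 88.7) had their best other marker on their own chromosome, against 9.27% of all marker pairs.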
